A study of Homo sapiens with 6 samples.

How the data were processed

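FT282 is an immortalised secretory epithelial cell line of the human fallopian tube. The study compared FT282 cells that carried an empty vector (EV) with FT282 cells made to express BORIS, the protein of the CTCFL gene and a paralog of the insulator protein CTCF. Of the 6 samples, 3 were chromatin immunoprecipitations (ChIP-seq), 1 was a sequenced input of EV cells and 2 were RNA-seq libraries. CTCF was precipitated in EV cells and in BORIS cells, and BORIS in BORIS cells. Each group held 1 sample, and no table of the input was used here.

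The deposited expression table gives FPKM values for both RNA-seq libraries, with the authors' own p-values and q-values and their mark of significance. Per the submitters' processing notes, Bowtie, TopHat2 and Cufflinks 2.0.0 were used and the genome build was hg19, with no role given for each tool. Per the labels' protocols, the RNA-seq libraries were made with 1 of 2 kits, and the kit of each library was not given in the sources used here. If the kits differed between EV and BORIS cells, that difference is confounded with the comparison. Whether each FPKM column holds 1 culture or pooled cultures was also not given. The table's spreadsheet origin had turned 28 gene names into dates, and those rows kept no usable name. Because of unreadable cells, the authors' fold column was not used, and ratios were computed from the FPKM values.

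The authors' deposited peak lists give, for each peak, a start, an end, a score and a position inside the peak. The peak caller, its threshold and the use of the input were not given in the sources used here, and the score has no stated unit. Scores were used only within a list. Read depth was unknown for the peak lists and for the FPKM values, whose low values did not fall on common steps of whole reads. No interval that needs a depth is given for them. A list at greater depth can hold more peaks, and small RNA genes can have high FPKM from few reads.

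For expression, log2((BORIS + 1)/(EV + 1)) was computed with a pseudocount of 1 FPKM, which understates the differences of low genes. Genes were counted as higher or lower when this ratio was at least 1 in size and the higher of the 2 values was at least 1 FPKM. With 1 library per group there was no test and no replicate check. For each gene list, the median ratio of its members with at least 1 FPKM in either library was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these 2 libraries only. A list was called above or below the random lists outside percentiles 2.5 and 97.5, given at least 5 measured members. Simulated lists of 25 genes were drawn from the 12496 genes of this comparison. Of these, 6.5% were called with no shift, 83.5% with a log2 shift of 0.1 and 100% with a shift of 0.2. The simulation shuffled ratios among genes of like expression and used fewer random lists. Its rates do not cover lists whose genes vary together or lists of other sizes. Of 949 list entries, 925 were found in the table, 18 of them through another symbol.

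Peaks were compared by overlap of at least 1 bp. Shares carry 95% Wilson intervals that cover counting error only. As a positional control, peaks were moved by 50 kb. CTCF peaks called in 1 list or in both were also compared within 10 equal parts of their own list by score, with a normal-approximation 95% interval for the difference. No genome sequence or strand was used here. A peak was therefore counted as near a gene end when its centre lay within 1 kb of either end of a gene span. Spans were those of the expression table, and this rule replaced the planned distance to the gene start. Of the 23278 rows, 5967 shared a span with another row. Such rows had the same peak status but were counted as separate genes, and a gene's own ends may lie inside a shared span. Coordinates of peaks are 1-based, and gene spans are as the table gives them. Genes on the chromosomes of the peak lists were joined to BORIS peaks by the same rule, and shares were ranked among 10000 random gene sets matched on mean expression.

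The named genes were CTCFL, CTCF and GALNT14, the 15 genes with the highest and the 15 with the lowest ratio, and the 2 members of each list with the largest ratio in either direction. Apart from the first 3, these needed an estimate marked usable, an official symbol and 1 FPKM, and the MIR, SNORD, SNORA and RNU families of small RNAs were left out. Small RNA genes below means these families. Named regions were the peaks within 10 kb of the GALNT14 and CTCFL spans, the peaks at the ends of the 30 genes named by size, and the 3 highest-scoring peaks of each class. The rules, the gene lists and the first set of alternatives were fixed before the data were examined. The alternatives were other pseudocounts, filters, scalings, thresholds, overlap rules, distances and subsets of peaks. A count without small RNA genes and with usable estimates alone was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.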

Results

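CTCF and BORIS occupancy and RNA levels were measured in FT282 cells carrying an empty vector (EV) and in FT282 cells expressing BORIS, also called CTCFL, a germ-line paralog of CTCF. The series title names motility, invasion, GALNT14 and CTCF occupancy as its subjects. The peak lists held 43162 CTCF peaks in EV cells, 44625 CTCF peaks in BORIS cells and 23653 BORIS peaks in BORIS cells, covering 16.5, 18.2 and 11.4 Mb. The expression table held 23278 rows, of which 12496 had at least 1 FPKM in either library. There was 1 library per group, so no value below has a replicate error, and differences describe these libraries.

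CTCFL stood at 0.00532 FPKM in the EV library and 53.3 FPKM in the BORIS library, in the direction the labels give. CTCF stood at 21.1 and 20.8 FPKM. GALNT14, an enzyme that starts mucin-type O-glycan chains, stood at 0.141 FPKM in EV cells and 8.16 FPKM in BORIS cells, a log2 ratio of 3.005. A relative, GALNTL1, was at 0.0881 FPKM in EV cells and 1.61 FPKM in BORIS cells. Of the 11 measured GALNT genes 6 were above 0 and 5 below, with a median of 0.00. The authors' deposited table marked 3 of them as higher and 0 as lower, GALNT14 among them. It did not mark CTCFL, which had the highest ratio of the named genes. Its marks carry no replicate error here and do not simply follow the size of the ratio.

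Besides CTCFL and GALNT14, the genes with the highest ratios included SERPINB2, an inhibitor of plasminogen activators, at 0.428 FPKM in EV cells and 12.2 FPKM in BORIS cells. COCH stood at 0.646 and 6.58 FPKM. CLGN, a testis chaperone, was at 2.17 and 12.5 FPKM, and TMEM200A at 0.121 and 3.11 FPKM. The STEAP family genes STEAP1 and STEAP2 stood at 0.348 and 1.06 FPKM in EV cells and at 3.37 and 4.47 FPKM in BORIS cells. ADD2, which encodes a cytoskeletal adducin, was at 0.0509 and 2.21 FPKM. The GABA receptor subunit GABRA5 was at 0.103 and 2.21 FPKM, and the integrin subunit ITGA4 at 0.237 and 2.30 FPKM. SLC22A17, SRPX, PDLIM3 and FOXA3 completed the 15, with log2 ratios of 1.51, 1.502, 1.39 and 1.41. The authors' deposited table did not mark FOXA3.

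Among the lowest genes were smooth muscle actins. ACTA2 stood at 697 FPKM in EV cells and 292 FPKM in BORIS cells, and ACTG2 at 5.23 and 1.496 FPKM. The natriuretic peptide gene NPPB was at 23.4 and 7.66 FPKM. SULF1, which trims sulfate from heparan sulfate, was at 17.9 and 6.18 FPKM. KRT17, a basal keratin, was at 14.2 and 5.72 FPKM, and IGFBP5 at 89.9 and 40.0 FPKM. KCNIP1, MYL7, CADM4, SCARNA18 and EDN2 had log2 ratios of -1.09, -1.08, -1.06, -1.05 and -1.05. SCARNA18 is a small Cajal body RNA outside the small RNA families that were left out, and the authors' deposited table marked neither it nor MYL7. The remaining 4, PCNA-AS1, URGCP-MRPS24, INO80B-WBP1 and TNFAIP8L2-SCNM1, are antisense or read-through genes that share reads with their neighbours. Their values are uncertain, and the authors' deposited table marked 0 of these 4. PCNA-AS1 is listed at 0 in BORIS cells.

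By the rule of size, 181 genes were higher and 117 lower with BORIS. Small RNA genes made up 124 of the former and 94 of the latter, and 144 of these 218 were listed at 0 in 1 library. Without small RNA genes and with usable estimates, 55 genes were higher and 19 lower. Most genes were close to equal, since 96.4% of the 11984 genes with 1 FPKM in both libraries lay within 0.5 log2 units of 0. The authors' deposited table marked 773 genes as higher and 883 as lower, and 76.0% of these 1656 lay within 0.5 log2 units.

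Genes of inflammation stood higher together in BORIS cells. Of 24 measured cytokine and NF-kB target genes, 22 were above 0, and the median log2 ratio of 0.35 lay above all 10000 matched random lists. IL8, a neutrophil chemokine, was at 129 FPKM in EV cells and 322 FPKM in BORIS cells, and CXCL6 at 36.6 and 80.7 FPKM. The authors' deposited table marked 15 of the 24 as higher and 0 as lower. Interferon response genes had a median of 0.17, again above all random lists, with 26 of 31 above 0. HERC5 was at 1.66 and 4.19 FPKM and IFI6 at 18.0 and 26.4 FPKM, and the authors' deposited table marked 13 as higher and 1 as lower.

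Matrix proteases and their inhibitors had a median of 0.10 (percentile 99.9), with SERPINE2 at 0.888 and 3.38 FPKM and the protease MMP7 at 2.87 and 5.72 FPKM. They went both ways, and the authors' deposited table marked 7 as higher and 4 as lower. Cholesterol synthesis genes had a median of 0.11 (percentile 99.9), with INSIG1 at 25.9 and 30.3 FPKM, while SC5DL was lower at 17.1 and 14.3 FPKM, and the authors' deposited table marked 0 of the 19 measured genes in either direction. The ribosomal protein genes, chosen as a reference, had a median of 0.07 (percentile 98.0), with RPL30 at 799 and 908 FPKM and RPS27 at 1.08 and 0.574 FPKM, and the authors' deposited table marked 0 of them. Medians of that size therefore also arose in a reference list, which lay just inside the range with a minimum of 5 FPKM (percentile 97.46).

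**Figure D1:**
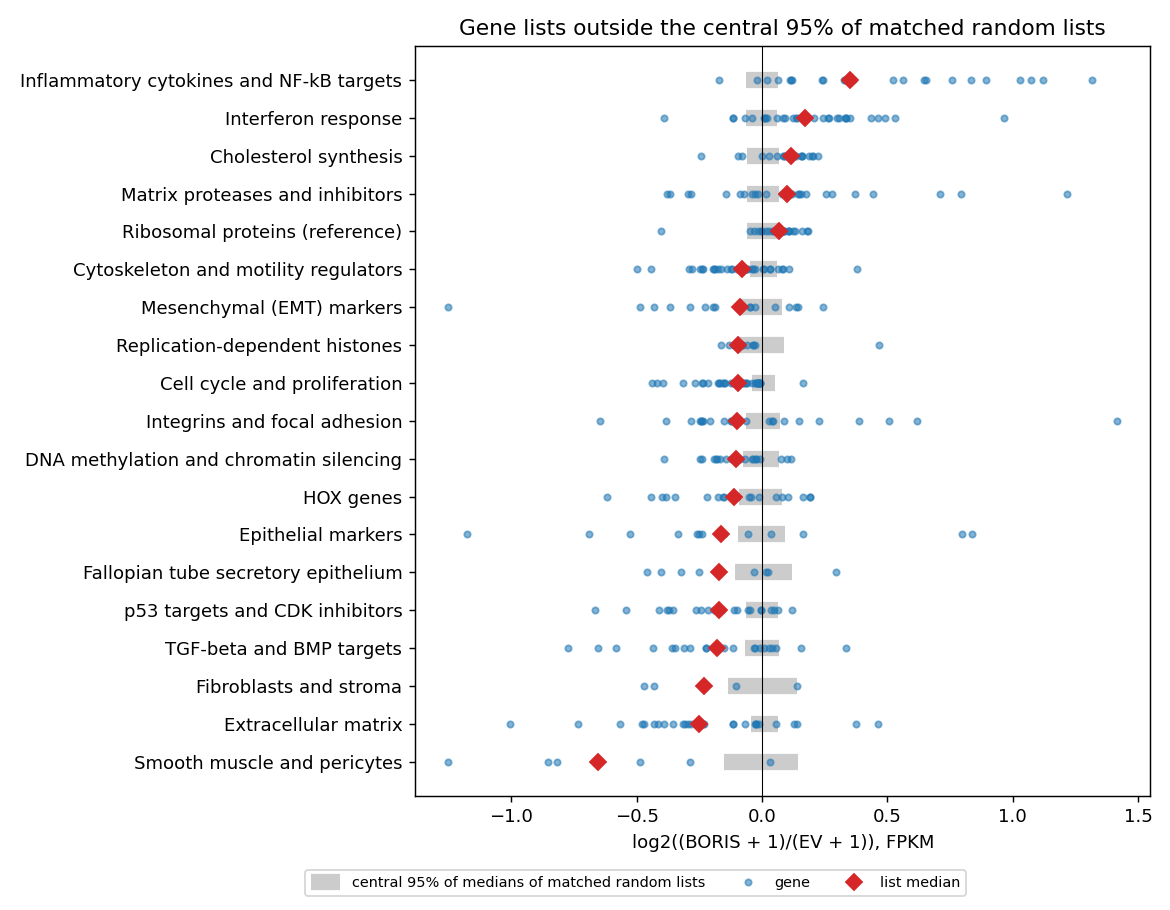
Log2 ratio of BORIS to EV (FPKM with a pseudocount of 1, x axis) for measured genes of the 19 lists outside the central 95% of matched random lists; dots are genes, diamonds list medians and grey bars the central 95% of random medians. Inflammatory genes lie highest, with a median of 0.35, and smooth muscle genes lowest, with a median of -0.65.

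Genes of contractile cells and matrix stood lower in BORIS cells. Of 6 measured smooth muscle genes 5 were below 0, the median was -0.65, and it lay below all random lists. LMOD1 was at 5.80 FPKM in EV cells and 2.77 FPKM in BORIS cells, and the authors' deposited table marked 5 of the 6 as lower. Extracellular matrix genes had a median of -0.25, below all random lists, with 23 of 28 below 0. COL6A2 was at 31.0 and 14.96 FPKM and THBS1, a matricellular glycoprotein, at 1825 and 1098 FPKM. The authors' deposited table marked 13 of these genes as lower and 2 as higher. Fibroblast genes had a median of -0.23 (percentile 0.28), with COL1A1 at 64.8 and 46.5 FPKM and PDGFRB at 1.38 and 0.763 FPKM. Mesenchymal genes had a median of -0.09 (percentile 2.07), with TAGLN at 2358 and 1680 FPKM. Cytoskeleton and motility genes had a median of -0.08 (percentile 0.21), with MYL9 at 748 and 530 FPKM and CDC42EP3 at 84.9 and 62.2 FPKM. In the authors' deposited table, 2 fibroblast, 5 mesenchymal and 5 cytoskeleton genes were marked lower, and 0, 0 and 1 were marked higher.

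Targets of TGF-beta and BMP and of p53 each lay below all random lists, with medians of -0.18 and -0.17. CTGF was at 210 and 133 FPKM and FST, an activin antagonist, at 2.73 and 1.18 FPKM. The cell cycle inhibitor CDKN1A was at 56.5 and 35.3 FPKM, and PHLDA3 at 39.2 and 26.6 FPKM. The authors' deposited table marked 8 TGF-beta and BMP targets as lower and 1 as higher, and 7 p53 targets as lower and 0 as higher. Cell cycle genes had a median of -0.10, below all random lists, and 38 of 39 lay below 0. Among them were MKI67 at 62.1 and 46.2 FPKM and CCND1 at 108 and 79.0 FPKM, and the authors' deposited table marked 5 as lower and 0 as higher.

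Epithelial genes had a median of -0.16 (percentile 0.08) but went both ways, with KRT17 lower and ELF3 higher at 2.47 and 5.20 FPKM. Secretory cell genes of the fallopian tube had a median of -0.17 (percentile 0.33), with MUC1 at 1.45 and 0.850 FPKM and WFDC2 at 1.28 and 0.661 FPKM. HOX genes had a median of -0.11 (percentile 0.79), with HOXC13 at 1.04 and 0.329 FPKM and HOXC6 at 2.38 and 1.48 FPKM. With a minimum of 5 FPKM both lists lay inside the random range, at medians of -0.01 (percentile 41.3) and -0.03 (percentile 38.4). DNA methylation and silencing genes had a median of -0.10 (percentile 0.32), with TET3 at 4.503 and 3.20 FPKM and MLL at 14.0 and 11.6 FPKM. Histone genes had a median of -0.09 (percentile 2.23), with HIST2H2BE at 49.7 and 44.3 FPKM but HIST3H2A higher at 11.9 and 16.9 FPKM. Of the 15 measured histone genes the authors' deposited table marked 0 as lower and 1, HIST3H2A, as higher. Integrin and focal adhesion genes had a median of -0.10 (percentile 0.30) and a mean of 0.02, as ITGA4 was higher and ITGA11 lower at 1.501 and 0.597 FPKM. For the epithelial, secretory, HOX, silencing and integrin lists, the authors' deposited table marked 5, 2, 3, 3 and 3 genes as lower and 2, 1, 0, 0 and 4 as higher, and left WFDC2 and HOXC6 unmarked. In all, 5 lists lay above and 14 below the central 95% of random lists. By chance, 1.55 of the 31 ranked lists would be expected if the genes within a list varied independently. Genes of a list can vary together, and some lists share members such as ACTA2, so the excess over 1.55 was not tested.

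The medians of 12 lists lay inside that range. They were antigen presentation (-0.05), CTCF and cohesin (-0.06), clustered protocadherins (-0.09), the GALNT family (0.00), housekeeping genes (-0.03), hypoxia and glycolysis (-0.06), immediate-early genes (-0.02), imprinted genes (-0.09), mesothelium (-0.09), O-glycan extension (0.04), unfolded protein stress (-0.05) and WNT (-0.05). Single members stood apart, such as SLC7A11 at 1.73 and 4.22 FPKM, SLC7A5 at 29.0 and 13.9 FPKM and SFRP1 at 3.11 and 1.21 FPKM. Of 41 cancer-testis antigen genes found, 0 reached 1 FPKM in either library. Of 45 meiosis and germ cell genes 3 did, including the meiotic cohesin REC8 at 54.6 and 62.8 FPKM. Ciliated cell, endothelial and leukocyte lists had 2, 4 and 2 measured genes, too few to rank. CDH5 was at 35.2 and 30.2 FPKM and CD68 at 1.48 and 2.26 FPKM. Mitochondrially encoded genes had 0 rows found under the symbols used.

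CTCF occupancy was compared between EV and BORIS cells. Of the CTCF peaks in EV cells 94.2% (95% interval 94.0 to 94.4) were also called in BORIS cells, and of those in BORIS cells 90.8% (90.6 to 91.1) were also called in EV cells. After moving the peaks by 50 kb the shares were 1.75% and 1.74%. This left 2490 peaks called in EV cells alone and 4085 called in BORIS cells alone. These were weak peaks, with median scores of 68 and 125 within their lists against 789 and 1172 for peaks called in both. The strongest peak called in BORIS cells alone lay on chromosome 17 at 6616564 to 6617171, 127 bp from an end of SLC13A5. Another, on chromosome 22 at 19711608 to 19711991, lay inside the span of GP1BB, and both overlapped a BORIS peak. The last of the 3 strongest, on chromosome 5 at 1667406 to 1667660, overlapped no BORIS peak. The strongest peak called in EV cells alone lay on chromosome 20 at 54032167 to 54032436, far from any gene end, and CBLN4 was the nearest gene.

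Many BORIS peaks lay at CTCF sites. In BORIS cells 65.6% (65.0 to 66.2) of them overlapped a CTCF peak, against 2.24% after the move by 50 kb. In EV cells, without BORIS, 62.4% (61.7 to 63.0) of the same places were CTCF peaks. The share in BORIS cells was 46.3% with 50% reciprocal overlap or with lists of equal size. CTCF peaks were called in neither cell population at 7937 BORIS peaks (33.6%), in BORIS cells alone at 968 and in EV cells alone at 203. The strongest BORIS peaks without CTCF in BORIS cells lay on chromosome 15 at 56535630 to 56536393, near an end of RFX7, on chromosome 22 at 20104476 to 20105069, at an end of DGCR8, and on chromosome 11 at 64546193 to 64546592, at an end of SF1. The DGCR8 peak overlapped a CTCF peak in EV cells.

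CTCF peaks called in BORIS cells alone overlapped a BORIS peak in 24.9% (23.6 to 26.2) of cases and those called in both in 36.0% (35.5 to 36.5). The direction turned once score was matched. Within parts of equal score, the share was 9.04 percentage points higher (7.38 to 10.7) for the peaks called in BORIS cells alone than for those called in both. The difference was smaller when location was held as well, at 3.45 points (1.96 to 4.94) more than 5 kb from gene ends and 4.93 points (-0.07 to 9.92) within 1 kb of them, where the interval includes 0. CTCF peaks called in EV cells alone overlapped a BORIS peak in 8.92% (7.86 to 10.1) of cases. Within parts of equal score, their share differed from that of peaks called in both by -12.5 percentage points (-14.0 to -10.9). With location held as well, the difference was -6.03 points (-7.35 to -4.70) more than 5 kb from gene ends and -16.6 points (-24.5 to -8.65) within 1 kb. By selection these places were not CTCF peaks in BORIS cells, the only cells with a BORIS precipitation. Their scores were matched in the EV list alone. A lower share may therefore arise in part from the selection.

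**Figure D2:**
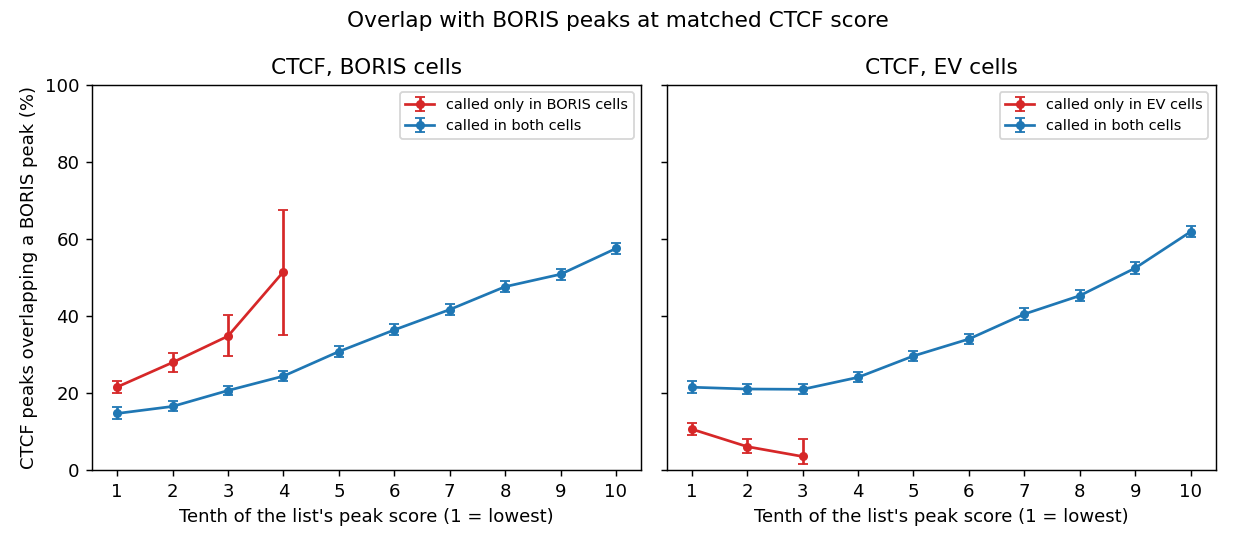
Share of CTCF peaks that overlap a BORIS peak (y axis, percent, with 95% Wilson intervals) by part of the list from lowest to highest score (x axis, parts with 20 or more peaks), in BORIS cells on the left and EV cells on the right. Within the lowest part, 21.6% of peaks called in BORIS cells alone and 14.7% of those called in both overlapped a BORIS peak.

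BORIS peaks lay near gene ends more often than CTCF peaks did. Within 1 kb of a gene end were 35.9% (35.3 to 36.6) of BORIS peaks, against 5.06% after the move by 50 kb, and 11.1% and 12.02% of CTCF peaks in EV and BORIS cells. The share was 57.5% (56.4 to 58.6) for BORIS peaks without CTCF in BORIS cells and 24.6% (23.9 to 25.3) for those with it. It was 5.30% (5.05 to 5.56) for CTCF peaks in BORIS cells without BORIS. Of the 1017 CTCF peaks called in BORIS cells alone that overlapped BORIS, 51.1% (48.1 to 54.2) lay near a gene end. As spans carry no strand here, starts and stops of genes were not told apart. The series held no BORIS precipitation in EV cells. Peaks of the BORIS list that would also arise without BORIS protein could therefore not be set apart, with or without CTCF.

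**Figure D3:**
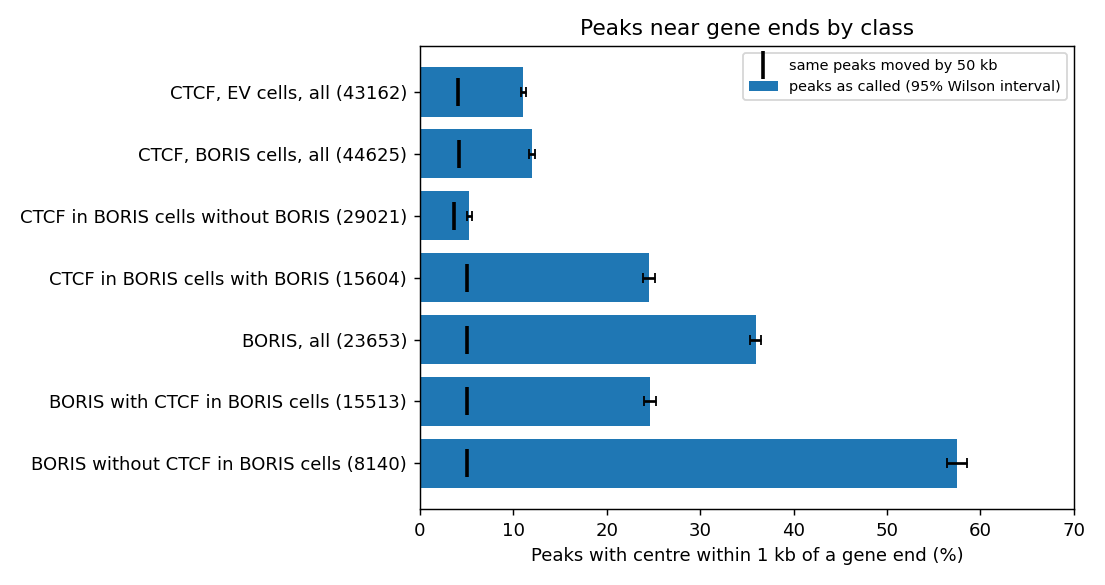
Share of peaks whose centre lies within 1 kb of a gene end (x axis, percent; bars with 95% Wilson intervals, number of peaks in brackets) by class, with black marks for the same peaks moved by 50 kb. BORIS peaks without CTCF reach 57.5% and CTCF peaks without BORIS 5.30%.

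At GALNT14, which spans chromosome 2 from 31133330 to 31361592 (hg19), CTCF peaks stood in EV cells at 31360882 to 31361101 and at 31361422 to 31361826, at the end with the higher coordinate. Both places were also CTCF peaks in BORIS cells, and a BORIS peak at 31360734 to 31361886 covered them. Counted from the lowest score, these CTCF peaks lay in part 3 of 10 of the EV list (scores 166 and 225). In the BORIS list they lay in part 5 (scores 909 and 877). A second BORIS peak lay beside it at 31359925 to 31360480 without CTCF. Inside the span, a CTCF peak at 31202602 to 31203125 was called in BORIS cells alone and overlapped a BORIS peak at 31202630 to 31202987. A further pair of CTCF peaks, at 31138411 to 31138709 and 31272190 to 31272429, was called in BORIS cells alone without BORIS. Near CTCFL, on chromosome 20, the same 4 places were CTCF peaks in both, and the 1 BORIS peak stood at 56101205 to 56101877, 1386 bp from a gene end.

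**Figure D4:**
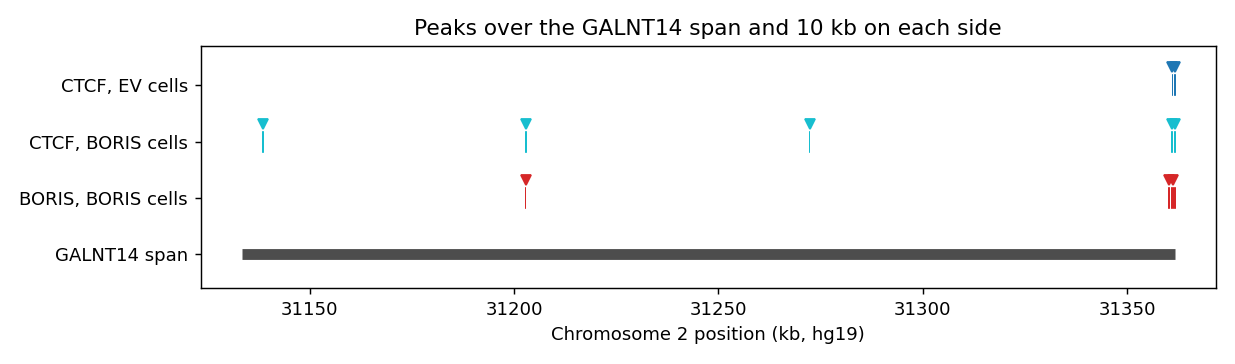
Peaks of the 3 lists along chromosome 2 (x axis, kb, hg19) over the GALNT14 span with 10 kb on each side; bars are peaks to scale and triangles mark their centres. Besides the CTCF peaks at the right end, 3 were called in BORIS cells alone, 1 of them with a BORIS peak.

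Of 12363 genes with 1 FPKM on the chromosomes of the peak lists, 57.8% had a BORIS peak within 1 kb of an end. Their median log2 ratio was 0.017 and that of the other genes -0.024, a small difference, and the first lay above all 10000 matched random sets. Among the 15 genes with the highest ratios, COCH, CLGN, STEAP1, ADD2, GABRA5, SLC22A17, SRPX, ITGA4, FOXA3, STEAP2 and GALNT14 had such a peak, and CTCFL, SERPINB2, TMEM200A and PDLIM3 had none. Of 176 genes higher by the rule, 56.2% (48.9 to 63.4) had a peak, inside the random range of 46.6 to 60.8%. That share moved above its random range within 5 kb of an end (75.0%), with the highest-scoring BORIS peaks (39.8%) and with a pseudocount of 0.1 (62.2%). Of 114 lower genes 36.0% had one, below the random range of 47.4 to 65.8%. Without small RNA genes and with usable estimates, a choice made after seeing the data, 41 of 54 higher genes (75.9%) had a peak, above the random range of 37.0 to 63.0%, and 8 of 19 lower genes (42.1%) did, inside the range of 31.6 to 78.9%.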

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

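The exclusion of small RNA genes was chosen after seeing the data, and the other settings before. With 1 sample per group, no replicate could be left out, and no paired analysis was possible because no result comes from replicated samples. The planned use of either gene end is identical to the rule used, so it was not run. The counts of 181 higher and 117 lower genes stayed within 1.5 times under other pseudocounts, filters and scalings. They were 104 and 57 with a log2 ratio of 2 or more, which is a stricter rule, and 55 and 19 without small RNA genes and with usable estimates. The log2 ratio of CTCFL was 8.99 and 11.76 with pseudocounts of 0.1 and 0.01 and 6.28 on the TPM scale, and that of GALNT14 was 5.10, 5.76 and 3.41, because a smaller pseudocount shrinks ratios of low genes less. The number of lists outside the random range was 19, and 16 with a minimum of 5 FPKM, where secretory epithelium, HOX genes and ribosomal proteins fell inside it. No list median and 0 of 94 named gene ratios changed sign where a call stood. For single genes this was fixed in advance and shows no robustness. A pseudocount cannot alter the sign of a ratio. The scalings moved ratios by little, as centring removed a median of -0.0014 and the TPM scale gave a median of -0.0198.

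Of CTCF peaks in EV cells, the share also called in BORIS cells was 92.8% with 50% reciprocal overlap, 93.5% with points inside the peaks within 100 bp, 96.4% for the highest-scoring 50% of each list and 95.2% at equal list size. For CTCF peaks in BORIS cells the values were 89.8%, 90.5%, 93.2% and 95.2%. When the highest-scoring 50% of a list was set against the whole other list, both shares were 100%. BORIS peaks overlapping CTCF in BORIS cells made up 46.3%, 61.9%, 57.9% and 46.3% under the same 4 settings, and in EV cells 44.4%, 59.4%, 56.0% and 45.7%, so most BORIS peaks overlapped CTCF under some of these settings and not under others. CTCF peaks called in BORIS cells alone overlapped BORIS in 13.9%, 19.8%, 23.7% and 37.2% of cases under the same 4 settings, and those called in EV cells alone in 5.95%, 9.44%, 17.9% and 27.0%. For CTCF peaks of BORIS cells called in both the shares were 25.8%, 34.2%, 31.2% and 46.5%, above those called in BORIS cells alone each time, as without matching for score. The gap between peaks of BORIS cells alone and of EV cells alone narrowed under all 4 settings, most for the highest-scoring 50%. Cutting lists by score turns peaks just under the cut into peaks of 1 list alone. BORIS peaks near gene ends made up 52.5% within 5 kb and 37.5% in the highest-scoring 50%.

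The share of higher genes with a BORIS peak was 75.0% within 5 kb of an end and 39.8% with the highest-scoring 50% of BORIS peaks. It was 75.9% without small RNA genes and with usable estimates. These shares lay at percentiles 99.2, 98.8 and 100 of matched random sets, against 73.0 by the planned rule. With a pseudocount of 0.1 the share was 62.2% (percentile 100.0), and with a minimum of 5 FPKM it was 52.9% (percentile 17.7). Whether this share stood above random sets thus depended on the setting. The cause was not tested, and small RNA genes were not left out without the limit to usable estimates. Only 2 higher genes outside the small RNA families lacked a usable estimate. The rise of the share to 75.9% thus came mostly from leaving small RNA genes out. The depth behind the peak lists and FPKM values was unknown, which limits what the smaller differences show.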

Other observations

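The tests on peaks within 1 kb of gene ends, small RNA reads, leukocytes and genes near 0 were chosen after the result was seen, and those on peaks more than 5 kb from gene ends, the CTCF antibody and BORIS peaks at inflammatory genes before. BORIS peaks also lay at some germ-line genes that stayed low. Of 45 meiosis and germ cell genes 10 had a BORIS peak within 1 kb of an end, among them DMC1, SYCP3, STAG3, SMC1B and TEX14, and 8 of these 10 were under 1 FPKM in both libraries. Of 41 cancer-testis antigen genes 2 had such a peak, CT45A1 and PRAME, and both were under 1 FPKM in both libraries. Among genes under 1 FPKM in both libraries, the share with a BORIS peak was 19.03% (18.2 to 19.8) over all 9397 such genes, 19.05% (9.98 to 33.3) for the 42 meiosis and germ cell genes and 4.88% (1.35 to 16.1) for the 41 cancer-testis genes.

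CTCF peaks called in BORIS cells alone overlapped BORIS peaks more often than CTCF peaks of like score called in both. More than 5 kb from the ends of gene spans the difference was 3.45 percentage points (1.96 to 4.94). This argues against pull-down of chromatin at those ends as the whole cause. Promoters inside a span were not set apart, so pull-down of promoter chromatin in general was not decided. Within 1 kb of gene ends, where 51.1% of the overlapping new peaks lie, the difference was 4.93 (-0.07 to 9.92), and promoter chromatin stays open there. A CTCF antibody that also takes up BORIS could not be decided: of the strongest part of BORIS peaks without CTCF in EV cells, 22.8% (20.2 to 25.7) had a CTCF peak in BORIS cells, and this share was 6.29% in the weakest part. Recruitment of CTCF by BORIS, and differences of depth or chromatin between the single libraries, stay open as well.

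Small RNA genes made up most genes past the rule of size. The authors' deposited table marked 0.459% of those 218 genes as significant. Among other genes past the rule with usable estimates, it marked 46 of 55 higher and 13 of 19 lower ones. Few reads on short genes may give so low a share. Rows without a usable estimate may give it too, and how many of the 218 these were was not counted. The share therefore does not decide the cause, and no biological explanation was tested.

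Inflammatory genes stood higher and contractile genes lower in BORIS cells. A factor per library moves all genes alike, and so by itself would not set lists on opposite sides of their matched random lists; other differences of normalization were not tested. Leukocytes in the culture are argued against, since the largest excess in BORIS cells among PTPRC, TYROBP, FCER1G, LYZ and CD3E was 0.0106 FPKM. Of the other leukocyte genes, CD68 went the other way, at 1.48 FPKM in EV cells and 2.26 FPKM in BORIS cells and marked higher in the authors' deposited table, and CD14 stood at 2.25 and 2.21 FPKM. A role of BORIS binding at these genes was not decided. A BORIS peak lay at an end of 69.6% of 23 inflammatory genes, inside the random range of 39.1 to 78.3%. The 16 genes with a peak all stood higher in BORIS cells, but so did 22 of all 24 measured genes. A difference in culture density, library kit or clone between single cultures may also give such a pattern and was not tested.

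A hypothesis is that having both BORIS and CTCF peaks at its ends goes with a gene being near 0 in EV cells and higher in BORIS cells. The BORIS and CTCF peaks did not have to overlap or lie at the same end. Of 51 genes under 0.5 FPKM in EV cells and at 1 FPKM or more in BORIS cells, small RNA genes left out, 66.7% had a BORIS peak at an end, against a random range of 29.4 to 56.9%. The excess lay in genes with both a BORIS and a CTCF peak at their ends (47.1%, random range 13.7 to 37.3%), while 19.6% had BORIS without CTCF, inside the random range of 7.84 to 27.5%. Of the 34 genes with a BORIS peak, 19 had CTCF at an end in EV cells and 10 had none in either. The other 5 had it in BORIS cells alone (ADD2, GP1BB, SLC27A2, SLC9A2 and SPSB4). CTCF was counted by peak calls here, without regard to score. Over genes with 1 FPKM and usable estimates, 0.240% (0.121 to 0.472) of 3339 genes with BORIS alone were higher by the rule, against 0.277% (0.159 to 0.484) of 4331 with no peak and 0.884% (0.608 to 1.28) of 3056 with BORIS and CTCF in both cell populations. Without BORIS, 0 of 464 genes with CTCF in both were higher (upper bound 0.821%), and the intervals with and without BORIS overlap. For CTCF in BORIS cells alone, the shares were 1.38% (0.632 to 2.97) of 436 genes with BORIS and 0.730% (0.129 to 4.02) of 137 without it. These intervals overlap too. Overlap is not a test of a difference, so a part played by BORIS was not decided in either comparison. With CTCF in both and BORIS, the authors' deposited table marked 315 genes higher and 137 lower, against 17 higher and 57 lower without BORIS. With CTCF in BORIS cells alone, it marked 44 higher and 23 lower with BORIS, and 7 higher and 18 lower without it. These opposite directions were not tested. With CTCF in EV cells alone, 0 of 141 genes were higher by the rule (upper bound 2.65%). Of the 16 genes with the reverse pattern 37.5% had a BORIS peak, inside their random range of 18.8 to 68.8%. Besides GALNT14, FOXA3 and ITGA4, the 51 held FGFR4, SPSB4, SLC27A2 and ZNF114, named after their values were seen. This was found and tested on the same data. It may reflect binding that raises these genes, or a preference of BORIS for chromatin that opened for another reason, and these data do not separate them.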
